A study of Mus musculus with 18 samples.

How the data were processed

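RNA of mouse embryonic fibroblasts was measured on 18 Affymetrix mouse expression arrays, 2 arrays for each of 9 groups: 3 genotypes (wt, heterozygous, homozygous) untreated or with 5 ng/mL TGFb1 for 4 h or 24 h. The deposited values are GCRMA intensities, background-corrected, normalized and summarized per probe set by the authors, per the submitters' processing notes, on a linear scale and with no GCRMA version stated. How the RNA was amplified, the array scan dates and the software of the scanner are not given in the sources used here, so no batch could be modelled. Groups were taken from the labels, and every one of the 18 columns was used.

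Values were converted to log2 without further normalization. Of 45101 probe sets 64 are controls, 34945 carry a single gene symbol, 932 several symbols and 9160 none; 34754 of those with a single symbol matched a RefSeq gene table, and 0 symbols were updated. A probe set was kept if its log2 value was at least 5 in at least 2 of the 18 arrays, which left 18958, of which 17442 had a single symbol. Each gene was represented by its brightest probe set with a single symbol, which gave 10078 genes. In each array 39.48 to 40.33% of probe sets lay above log2 5 (17780 to 18164 probe sets), and the median linear intensity was 8.416 to 9.163, so changes of dim genes cannot be measured well. Where both arrays of a group lay under log2 5 the change is given as a bound on the fold, from that level to the other group, without a fold where the other group's mean also lies under it. An interaction with such a group is given without a size. In 1 of the 2 arrays of a group these genes lay under that level and their sizes are uncertain: Sema7a, Pdgfb, Pdgfra, Pag1, Palmd and Arc in wt responses, Ccn3, Usp18 and Rtl3 at 24 h in heterozygous cells, Egr3 in wt cells at 24 h, Fosb at 4 h in both mutants and Dclre1a in an interaction. In the genotype comparisons they are Clec4n, Ly86, Mrc1, Pik3ap1 and Vegfd.

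Comparisons were made in R 4.3.3 with limma 3.58.1. A linear model with a mean for each of the 9 groups was fitted to all 18 arrays (9 residual degrees of freedom, median prior degrees of freedom 3.78), with moderated two-sided tests (eBayes with an intensity trend). P-values were adjusted by Benjamini-Hochberg over the 10078 genes of a comparison, and a gene was called at an adjusted p under 0.05. The 13 comparisons were TGFb against untreated at each time in each genotype, the 3 genotype comparisons of untreated cells, and 4 interactions (mutant response minus wt response). They were fixed before the data were examined, with the filter, the gene lists, the named-gene rule and most alternatives. The 3 comparisons of 24 h with 4 h were added after the data were seen.

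Gene lists were 31, fixed before the data were examined, with 559 genes of which 421 were measured. The 27 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with a correlation estimated from the arrays; fry was run beside them. List members are counted as past the threshold over all genes, and as adjusted over the list alone. Response lists are the genes called in 1 mutant genotype and were tested in the other mutant against wt. The size of the response is the slope through 0 of the mutant on the wt log2 fold changes.

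Named genes follow a rule fixed before the data were examined. Among called genes whose replicates do not overlap, the 10 largest rises and the 10 largest falls are named for both wt responses and for each mutant against wt, and at most 5 each way elsewhere. To these are added 10 key genes, of which 9 were measured, and up to 4 called members of each list with the largest change. Where nothing passes, the 5 genes with the smallest unadjusted p are given. Predicted genes and clones are left unnamed.

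Alternatives were no filter, a mean log2 of at least 6, the mean of a gene's probe sets, leaving out probe sets marked as cross-hybridizing, quantile normalization, equal array medians, log2 of the value plus 16, no intensity trend, array weights, only the groups compared and a replicate block over all groups or within genotype. Each array was also left out in turn. Added after the data were seen were a crossed block, a covariate for the sex class of the array and a covariate for the mean of the macrophage markers. Tests of other explanations were chosen after the results were seen. The fit was tested on simulated data with known changes among 10078 genes, 67 of 1.5-fold, 67 of 2-fold and 66 of 4-fold: of 2-fold changes 68.7% were recovered for wt at 24 h, 65.7% for homozygous against wt and 44.8% for the interaction at 24 h. Of 1.5-fold changes the fit recovered 31.3%, 38.8% and 19.4%, with 4, 5 and 9 false calls. The simulated noise had the same spread in every group. In the real arrays the wt pairs varied more than the mutant pairs, and each simulated comparison involves wt. These rates may therefore be too favourable.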

Results

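The series asked how mouse embryonic fibroblasts of 3 genotypes respond to TGFb1, a secreted ligand whose type I receptor TGFBR1 phosphorylates the transcription factors SMAD2 and SMAD3. The fibroblasts were prepared from E12.5 to E14.5 embryos after removal of the head, the liver and blood clots. They were wt, heterozygous or homozygous for a mutant that the labels call constitutively active. The series title places a point mutation in TGFBR1, while the design text names the mutant TGFb1, so it is called here only the mutant. Cells were left untreated, which the design text calls vehicle without giving a duration, or received 5 ng/mL TGFb1 for 4 h or 24 h. Each of the 9 groups had 2 arrays, 18 arrays in all. Every error printed with a fold change is the standard error of the limma fit, for 2 arrays against 2 or, in an interaction, for 4 groups of 2. The fit pooled the spread of each gene over all 9 groups, so an error is not that of the compared arrays alone. No label says that the 2 arrays of a group came from separate cultures or embryos, so the p-values measure only the spread between these arrays. Sex-linked genes, described below, differ within each wt and each homozygous pair, so those pairs are not repeats of the same RNA. For the heterozygous pairs they do not settle it. Replicates correlated at r = 0.993 to 0.998 across genes, which are not independent replicates. The standard deviation between replicates, as a root mean square over genes, was 0.379, 0.387 and 0.321 log2 in the untreated, 4 h and 24 h wt pairs and 0.183 to 0.222 log2 in the mutant pairs. With a pooled spread, errors and p-values may therefore be too small where wt arrays are compared and too large within the mutants.

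Genes of TGFb signalling, matrix and contraction were measured at high levels in every array. Tgfbr1, the gene of the type I receptor, ranged from 10.1 to 10.94 log2 over the 18 arrays, a level that says nothing about the mutation itself. Acta2, smooth muscle actin, lay between 15.27 and 15.51, Ccn2, a matricellular TGFb target, between 15.51 and 15.86, and Col1a1, a chain of type I collagen, between 14.64 and 15.63. Neither Acta2 nor Ccn2 passed the test in any treatment or genotype comparison. At such intensities the number of arrays and the upper end of the signal scale both limit what can be seen. Of the 10 key genes fixed before the data were examined, 9 were measured.

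In wt cells at 4 h, TGFb raised Il11, a cytokine of the IL-6 family, by 4.19 ± 0.28 log2 (18.3-fold, adjusted p = 2.45e-06) and Lce1f, a cornified envelope gene, by 5.18 ± 0.20 (36.2-fold, 2.2e-08). Sema7a, a GPI-anchored semaphorin, rose by 4.94 ± 0.45, Aldh1a3, a retinaldehyde dehydrogenase, by 4.64 ± 0.64, Pdgfb, a growth factor for mesenchymal cells, by 3.33 ± 0.54 and the forkhead gene Foxs1 by 3.23 ± 0.50. Fam110c rose at least 7.06-fold (adjusted p = 0.00218), the chemokine Ccl17 at least 2.46-fold (0.00263) and the immediate early gene Arc at least 1.49-fold (0.00349), as bounds because both untreated arrays lay under the dim level. The largest falls were those of Rspo2, a secreted enhancer of Wnt signalling (-3.68 ± 0.46), Gas1, a co-receptor for hedgehog ligands (-3.23 ± 0.34), Pdgfra, the PDGF receptor alpha (-3.14 ± 0.32), and Ptx3, a secreted pattern recognition protein (-2.81 ± 0.22). Pag1 (-2.77 ± 0.35), Palmd (-2.62 ± 0.39) and Dhrs3, a retinaldehyde reductase (-2.39 ± 0.19), also fell, and Tifa was called lower (adjusted p = 7.82e-05) with both group means under the dim level, so without a fold. The transcriptional cofactor Eya1 fell at least 3.38-fold (adjusted p = 0.000594) and Rarb, a retinoic acid receptor, at least 1.06-fold (2.52e-05).

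The 23 measured TGFb/Smad target and feedback genes had a positive median in wt cells at 4 h (0.432), with 12 higher, 1 lower and 10 not past the threshold (12 higher and 2 lower adjusted over the list alone). Camera, which compares a list with all other genes, gave adjusted p = 3e-06 for this list, and adjusted p = 0.0201 with an estimated correlation. Its members included Junb (1.54), the transcription factor Snai1 (1.45), Tgfb1 itself (1.35 ± 0.10), the inhibitory Smad gene Smad7 (0.87 ± 0.21) and the corepressor Skil (0.43 ± 0.09). Of the other key genes, Tgfbr1 rose by 0.55 ± 0.10 on its brightest probe set, with 1 of its 2 other probe sets at -0.31, Col1a1 fell by 0.42, with its other probe set at 0.087, and Id1 stood at 0.59 ± 0.34 (adjusted p = 0.242). Secreted growth factors and cytokines rose in 9 and fell in 3 of 23 cases (9 and 4 adjusted over the list alone; camera adjusted p = 0.0174, adjusted p = 0.739 with an estimated correlation), among them Lif (2.81), Fgf2 (2.54) and Il6 (2.52). Immediate early and AP-1 genes rose in 8 and fell in 1 of 17 cases (9 and 1 adjusted over the list alone; 0.00477, and adjusted p = 0.49 with an estimated correlation), including Egr2 (2.75) and Fosl1 (1.26), and Fosb, whose untreated and treated arrays all lay under the dim level. Limb bud and blastema mesenchyme genes fell in 6 of 12 cases and rose in 0 (9 and 0 adjusted over the list alone), with camera adjusted p = 0.000764 and adjusted p = 0.0292 with an estimated correlation. Gas1, the homeobox genes Shox2 (-1.38), Meis2 (-1.30) and Meis1 (-0.91) led that list.

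Other groups were split at 4 h in wt cells, with no camera call. Of 22 TGFb and BMP receptor, ligand and Smad genes 4 rose and 6 fell, among them the activin subunit Inhba (1.37), Fstl3 (1.06), Inhbb (-1.78) and the co-receptor Tgfbr3 (-2.05). Matrix proteases and inhibitors rose in 4 and fell in 2 of 18 cases, including Plaur (1.48), Mmp9 (1.45), Adamts5 (-1.95) and Adamts1 (-1.54). Contractile and myofibroblast genes rose in 3 of 22 cases: Itga5 (1.60), the fibronectin receptor subunit, Smtn (0.97) and Synpo2 (0.82). Serum response factor and MRTF-related genes rose in 5 and fell in 1 of 14 cases (median 0.112, camera adjusted p = 0.134), with Srf itself at 0.85 ± 0.13. The 10 inflammatory and NF-kB genes had 3 higher and 1 lower, with Tnfaip3 at 1.42 and the adhesion molecule Vcam1 at -1.53 (camera adjusted p = 0.336).

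In limma 2108 of 10078 genes passed in wt cells at 4 h, 956 higher and 1152 lower, of which 199 and 246 changed by over 2-fold. This count changed with the fit. With only the groups compared 24 genes passed, and with array weights 194. The same settings gave 5522 and 5860 in place of 3795 for homozygous cells, whose arrays varied less. The cause was not tested. Without replicate 2 of the treated wt arrays the count was 967, without replicate 1 it was 3382, and without replicate 1 of the untreated wt arrays it was 1154.

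**Figure D1:**
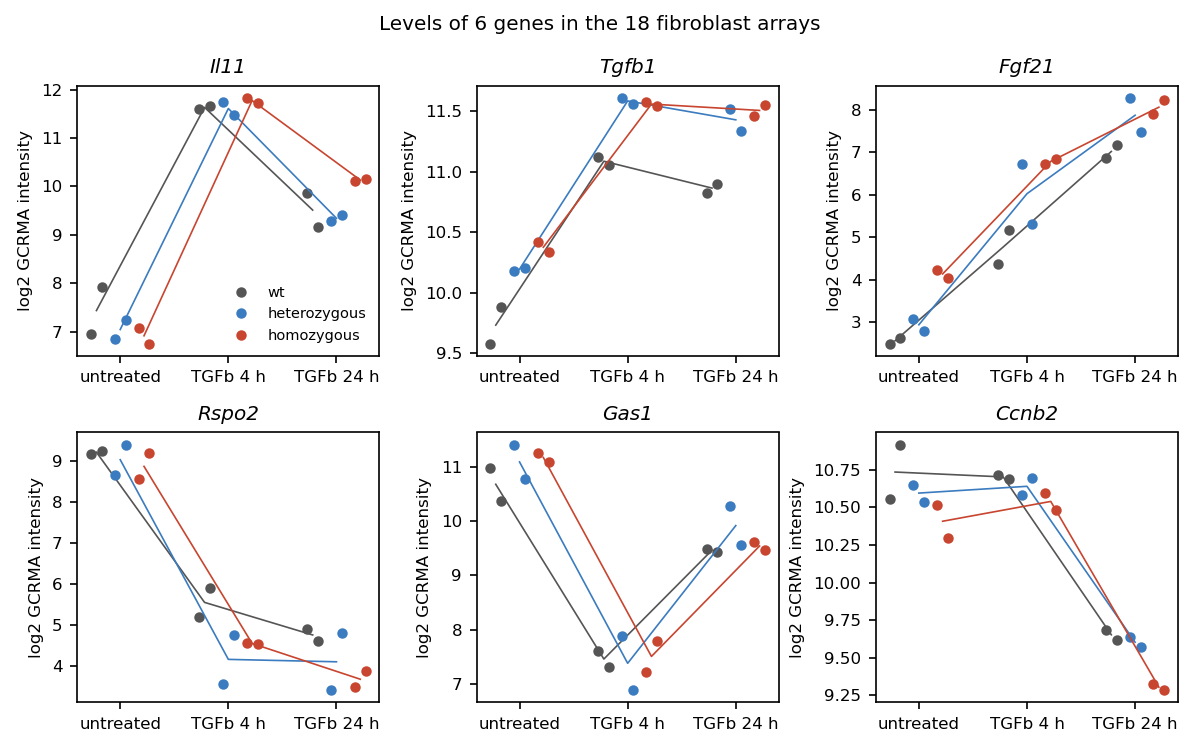
Levels of 6 genes, in log2 GCRMA intensity on the vertical axes, against treatment on the horizontal axes; each point is 1 of the 18 arrays, coloured by genotype, and lines join the group means. Il11 reached its highest level at 4 h, up to 11.82, and Fgf21 at 24 h, Rspo2 and Gas1 were lower at both times than untreated, and Ccnb2 was lower at 24 h in all 3 genotypes.

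At 24 h in wt cells a different set of genes led. Fgf21, a secreted hormone of the FGF family, rose at least 4.06-fold (adjusted p = 2.65e-05), Olfm2 at least 5.75-fold (3.65e-05), the efflux transporter Abcb1a at least 2.37-fold (0.000171) and arginase 1, Arg1, at least 1.78-fold (0.00267). Aldh1a3 was still higher, by 3.74 ± 0.64, and Cdh6, a cadherin, rose by 3.10 ± 0.29, the gelatinase Mmp9 by 2.86 ± 0.33 and the R-spondin receptor gene Lgr6 by 2.84 ± 0.28. The bounded falls were those of Rspo2, at least 18.7-fold (6.73e-05), Rtl3, at least 16.4-fold (0.00128), Lmcd1, at least 4.39-fold (0.0081), Cbr2, at least 3.32-fold (0.000373), and the lymphangiogenic factor Vegfd, at least 3.27-fold (0.000134). Ndnf (-3.91 ± 0.52), the matricellular gene Ccn3 (-3.69 ± 0.58), Ptx3 (-3.40 ± 0.22) and the interferon-induced gene Rtp4 (-3.34 ± 0.83) fell as well. Among the key genes Il11 (2.07 ± 0.28), Tgfb1 (1.13 ± 0.10) and Skil (0.95 ± 0.09) were higher, Id1, a BMP target, was lower (-1.24 ± 0.34), and Tgfbr1 (0.18), Smad7 (0.18) and Col1a1 (0.33) did not pass.

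TGFb/Smad target and feedback genes had 9 higher and 1 lower of 23 at 24 h (12 and 1 adjusted over the list alone), with camera adjusted p = 1.55e-08 and adjusted p = 0.00764 with an estimated correlation. Pdgfb (2.32), Bhlhe40 (1.57) and Spsb1 (1.36) rose, and Tgfbi, an extracellular matrix protein gene, fell (-2.02). All 19 measured mitosis genes fell, among them Ccnb2 (-1.08), Cenpf (-1.03), Plk1 (-1.02) and Birc5 (-1.02), with camera adjusted p = 3.73e-14 but adjusted p = 0.234 with an estimated correlation. DNA replication genes fell in 8 of 19 cases and rose in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 0.000709, adjusted p = 0.478 with an estimated correlation), for example Gins2 (-1.03). Limb bud and blastema mesenchyme genes fell in 6 of 12 cases (6 adjusted over the list alone; 0.000697, and adjusted p = 0.0328 with an estimated correlation): Prrx2 (-1.48), Gas1 (-1.22), Ptch1 (-1.04) and Prrx1 (-0.75) fell most.

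Collagens and extracellular matrix genes had 5 higher and 3 lower of 26 at 24 h in wt cells (7 and 3 adjusted over the list alone; camera adjusted p = 0.00417, adjusted p = 0.503 with an estimated correlation). Col7a1 (1.55), the anchoring fibril collagen, and Eln (1.09), elastin, rose, and the type VI collagen genes Col6a2 (-1.39) and Col6a1 (-0.98) fell. Collagen processing and cross-linking genes had 2 higher, Plod2 (1.15) and Bmp1 (0.65), and 1 lower, Pcolce (-0.45), of 13 (3 and 1 adjusted over the list alone; 0.0415, and adjusted p = 0.478 with an estimated correlation). Interferon-stimulated genes fell in 2 of 10 cases, Gbp2 (-2.76) and Ifit2 (-1.07), with a median of -1.778 (0 higher and 6 lower adjusted over the list alone; 0.00207, and adjusted p = 0.478 with an estimated correlation). The 11 macrophage and blood cell markers had a median of -0.493 in the same comparison, with 0 higher and 1 lower. Antioxidant and detoxification genes fell in 5 of 15 cases (7 adjusted over the list alone; 0.00326, and adjusted p = 0.202 with an estimated correlation), led by Gstm1 (-1.61) and Nqo1 (-1.32). Lists without a camera call still held large changes: of 10 adipogenesis genes Lpl (-1.82), Cd36 (-1.80) and Fabp4 (-1.79) fell and Plin2 (1.05) rose (median -0.497, camera adjusted p = 0.303). Of 22 receptor, ligand and Smad genes 5 rose and 4 fell, with Tgfbr3 at -3.15 and Bmp4 at -1.77. Of 22 contractile genes only Itga5 (0.76) rose, and Mylk (-2.45) and Myl9 (-0.45) fell.

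In limma 1175 genes passed at 24 h in wt cells, 455 higher and 720 lower, of which 135 and 237 changed by over 2-fold. With only the groups compared 75 genes passed, with array weights 324 and with the macrophage marker covariate, added after the data were seen, 1826. Without replicate 2 of the treated wt arrays 599 passed, without replicate 1 760, and without replicate 1 of the untreated wt arrays 1881. The direct comparison of 24 h with 4 h, added after the data were seen, called 3456 genes in wt cells, 1517 higher and 1939 lower. Of 17 immediate early genes 13 were lower at 24 h than at 4 h, with Egr3 at -4.13 and Fosl1 at -1.79 (camera adjusted p = 1.76e-05, adjusted p = 0.305 with an estimated correlation). That comparison called 0 genes with only the 2 groups in the limma fit and 1544 with array weights, and 1958 without replicate 2 of the 4 h arrays.

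**Figure D2:**
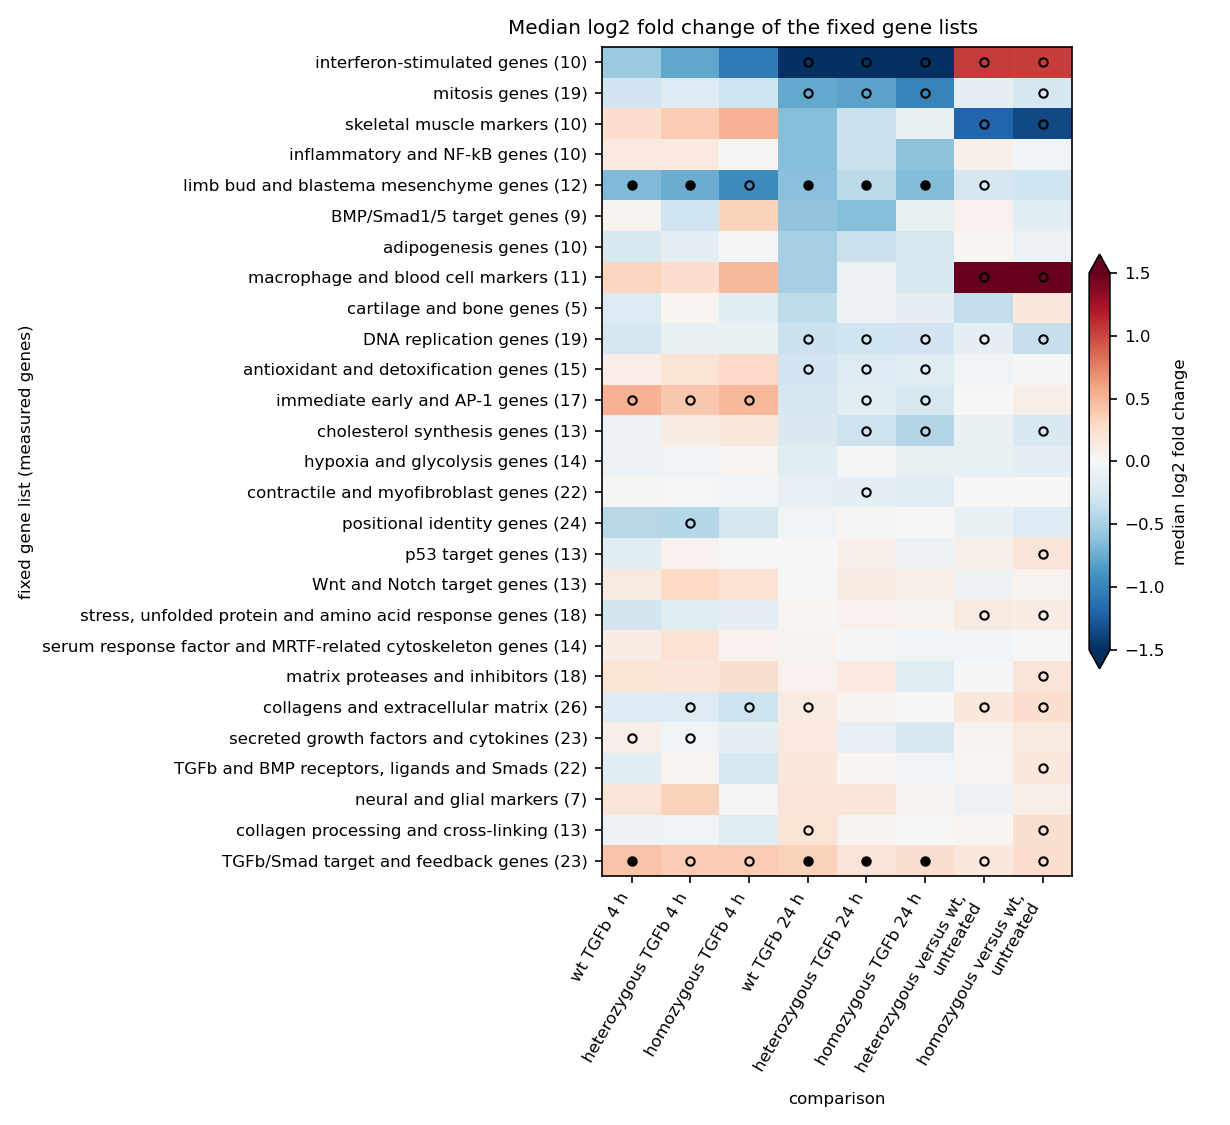
Median log2 fold change (colour, scale limited to -1.5 and 1.5) of the 27 fixed gene lists on the vertical axis, with the number of measured genes, in 8 comparisons on the horizontal axis; a circle marks a camera call and a filled circle a call also made with an estimated correlation. TGFb/Smad target and feedback genes had positive medians in all 8 comparisons, and in wt cells mitosis genes had a median of -0.765 at 24 h.

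At 4 h Lce1f, Il11, Sema7a, Rspo2 and Gas1 were among the largest changes in heterozygous and homozygous cells as in wt cells, beside genes that were not among the largest in wt cells, such as Serpinb2, Ifit1 and Irgm2. Lce1f rose by 5.41 ± 0.20 and 5.59 ± 0.20 in heterozygous and homozygous cells, Il11 by 4.56 ± 0.28 and 4.86 ± 0.28, and Sema7a at least 38.8-fold (adjusted p = 4.31e-06) in heterozygous and by 5.16 ± 0.45 in homozygous cells. Serpinb2, a serine protease inhibitor, rose at least 7.66-fold (7.15e-05) and 6.42-fold (4.64e-05). Rspo2 fell at least 16.4-fold (1.95e-05) and 14.7-fold (3.75e-05), Gas1 by 3.72 and 3.67 log2, and the interferon-induced genes Ifit1 at least 3.05-fold (0.00274) and 3.80-fold (0.000911) and Irgm2 at least 4.93-fold (0.00215) and 5.28-fold (0.00106). Arc, an immediate early gene, rose at least 3.05-fold (0.000288), and Stat2, a mediator of interferon signalling, fell at least 3.78-fold (0.00027) in homozygous cells, while Rarb fell at least 1.81-fold (4.31e-06) in heterozygous cells. Of the key genes, Tgfb1 rose by 1.39 ± 0.10 and 1.18 ± 0.10, and Col1a1 fell by 0.38 and 0.61. Smad7 (0.86 ± 0.21) and Id1 (1.61 ± 0.34) passed in homozygous cells, with 0.37 ± 0.21 and 0.83 ± 0.34 in heterozygous cells, and Skil stood at -0.09 and -0.07 without passing. Tgfbr1 passed at 0.39 ± 0.10 and 0.43 ± 0.10 on its brightest probe set, but the mean of its probe sets gave -0.038 and -0.36 and did not pass.

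Among TGFb/Smad target and feedback genes 11 were higher and 2 lower, of 23, in heterozygous cells at 4 h (11 and 2 adjusted over the list alone; camera adjusted p = 0.0123, adjusted p = 0.166 with an estimated correlation). In homozygous cells 13 were higher and 2 lower (13 and 3; 0.0354, and adjusted p = 0.323 with an estimated correlation). Limb bud and blastema mesenchyme genes fell in 8 of 12 cases in heterozygous cells (8 adjusted over the list alone; 0.000629, and adjusted p = 0.0427 with an estimated correlation). In homozygous cells 9 of 12 fell (9, with 2 higher; 0.00146, and adjusted p = 0.0742 with an estimated correlation). Collagens and extracellular matrix genes fell in 5 of 26 cases in heterozygous cells (4 adjusted over the list alone; 0.035, and adjusted p = 0.886 with an estimated correlation). In homozygous cells 12 fell (12; 0.00146, and adjusted p = 0.873 with an estimated correlation), for example Col12a1 (-0.76 and -0.90) and Col3a1 (-0.39 and -0.53). Immediate early genes rose in 8 and fell in 2 of 17 cases in heterozygous cells (9 and 2 adjusted over the list alone; 0.0181, and adjusted p = 0.724 with an estimated correlation). In homozygous cells 9 rose and 1 fell (10 and 2; 0.0377, and adjusted p = 0.873 with an estimated correlation). Fosb rose at least 1.16-fold (adjusted p = 0.000384) and 1.21-fold (0.000241). In heterozygous cells the growth factor list was also called (9 higher, 2 lower of 23; 9 and 2 adjusted over the list alone; 0.045, and adjusted p = 0.8 with an estimated correlation), with a camera direction up and a median of -0.07. The positional identity list was called lower there (3 higher, 5 lower of 24; 3 and 6 adjusted over the list alone; 0.045, and adjusted p = 0.8 with an estimated correlation), with Meox1 at 2.41 and Foxd1 at -1.69.

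At 24 h Fgf21 rose at least 7.32-fold (adjusted p = 1.77e-05) in heterozygous and 8.36-fold (6.95e-05) in homozygous cells, Olfm2 at least 8.28-fold (1.77e-05) and 8.84-fold (1.56e-05), Abcb1a at least 3.14-fold (0.000197) and 4.68-fold (6.25e-05) and Arg1 at least 2.91-fold (0.000746) and 1.75-fold (0.00269). Camk4, a calmodulin-dependent kinase, rose at least 2.32-fold (8.76e-05) in heterozygous cells. Rtl3 fell at least 20.4-fold (0.000931) in homozygous cells and was called lower in heterozygous cells (0.00141), without a size because its 2 treated arrays lay at 2.169 and 5.204 log2, Rspo2 at least 16.4-fold (4.41e-05) and 14.7-fold (2.82e-05), Ccn3 by 4.14 log2 and at least 14.5-fold (0.000623) and Ifit1 at least 3.05-fold (0.00984) and 3.80-fold (0.00269). Tgfb1 (1.23 ± 0.10 and 1.13 ± 0.10), Skil (0.59 ± 0.09 and 0.62 ± 0.09) and Il11 (2.30 ± 0.28 and 3.21 ± 0.28) were higher. Smad7 (0.35 and 0.60), Id1 (-0.94 and -0.25), Col1a1 (0.07 and -0.03) and Tgfbr1 (0.03 and 0.06) did not pass.

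All 19 mitosis genes fell in both mutant genotypes at 24 h, with medians of -0.807 and -1.004 (camera adjusted p = 3.19e-23 and 3e-22), and adjusted p = 0.0981 and 0.11 with an estimated correlation. Of the 23 TGFb/Smad target and feedback genes 6 were higher and 0 lower in heterozygous cells (10 and 2 adjusted over the list alone; 1.93e-05, and adjusted p = 0.0246 with an estimated correlation). In homozygous cells 7 were higher and 1 lower (10 and 1; 2.7e-06, and 0.0127). Limb bud and blastema mesenchyme genes fell in 3 of 12 cases in heterozygous (5 adjusted over the list alone; 9.65e-06, and adjusted p = 0.0178 with an estimated correlation) and 4 in homozygous cells (8; 8.37e-06, and 0.0127), with Prrx1 at -0.84 and -0.92. Interferon-stimulated genes fell in 5 of 10 cases in heterozygous (9 adjusted over the list alone; 8.5e-08, and adjusted p = 0.153 with an estimated correlation) and 4 in homozygous cells (10; 9.41e-07, and 0.307). Usp18 stood at -4.95 ± 1.33 in heterozygous cells, and Gbp2 at -2.50 and -2.65 in the 2 genotypes. The macrophage markers in the same comparisons had medians of -0.086 and -0.226. DNA replication genes fell in 3 and 4 of 19 cases (9 and 6 adjusted over the list alone; 6.52e-06 and 0.000218, and adjusted p = 0.283 and 0.468 with an estimated correlation). Antioxidant genes fell in 5 and 3 of 15 cases (5 and 4 adjusted over the list alone; 0.0029 and 0.0429, and adjusted p = 0.123 and 0.329 with an estimated correlation). Immediate early genes fell in 7 and 6 of 17 cases and rose in 1 and 1, Egr2 (8 and 6 lower, 1 and 2 higher adjusted over the list alone; 6.57e-05 and 0.0045, and adjusted p = 0.123 and 0.329 with an estimated correlation). Cholesterol synthesis genes had 0 of 13 past the threshold and medians of -0.313 and -0.444 (0.00293 and 0.00733, and adjusted p = 0.544 and 0.639 with an estimated correlation). Contractile genes were called lower in heterozygous cells, with 1 higher and 1 lower of 22 (1 and 3 adjusted over the list alone; 0.0298, and adjusted p = 0.644 with an estimated correlation).

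In limma 2904 genes passed in heterozygous and 3795 in homozygous cells at 4 h, and 712 and 867 at 24 h. The same 772 genes were higher and the same 777 lower at 4 h in all 3 genotypes, where 30.1 and 26.6 would be shared by independent lists of those sizes, and at 24 h 191 and 300, against 0.415 and 1.63. No gene was called in opposite directions in any pair of genotypes at either time (0 in limma, of 10078 genes). Each genotype had its own untreated arrays, so these lists share no control. Leaving out any array of a comparison gave 1554 to 2082 and 2163 to 2513 genes at 4 h and 303 to 443 and 379 to 450 at 24 h. With array weights the homozygous count at 4 h was 5860 and the 24 h counts were 1587 and 2726, and with only the groups compared the homozygous 24 h count was 2037.

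Whether the mutants respond more or less to TGFb than wt cells was asked with an interaction term per mutant and time. In limma 0 of 10078 genes passed in any of the 4 interactions, with 347 (heterozygous 4 h), 311 (heterozygous 24 h), 847 (homozygous 4 h) and 577 (homozygous 24 h) genes at an unadjusted p under 0.05. The gene nearest to the threshold was Dusp14, a dual-specificity phosphatase, at 4 h in homozygous cells (1.14 ± 0.16, adjusted p = 0.0635). It was followed there by Prrc2a (-0.98), Pomp (0.51), Dclre1a (-1.37) and Dhrs7 (0.97), each at adjusted p = 0.276. In heterozygous cells the smallest unadjusted p were those of Dusp14 (0.78), Tifa, Iqsec1 (-1.11), Skil (-0.53) and Apbb1ip (1.10) at 4 h, each at adjusted p = 1. At 24 h they were Steap1 (0.75), Bscl2 (0.70), Rnf10 (-0.61), Ankrd13d and Dleu7, each at 0.999. In homozygous cells at 24 h they were Endod1 (-0.88), Serpinb9b (1.17), Pif1, Insig2 (0.69) and Plagl2 (-0.98), each at 0.79. Tifa, Ankrd13d, Dleu7 and Pif1 are given without a size because both arrays of a group lay under the dim level. Among the 9 measured key genes the smallest adjusted p was 0.491, for Skil at 4 h in homozygous cells (-0.50 ± 0.13), and Il11 at 24 h in homozygous cells stood at 1.14 ± 0.39 (0.824). The median 95% interval of an interaction reached 0.503 log2 to either side, and in simulated data 44.8% of genes with a 2-fold interaction were recovered for homozygous cells at 24 h. Those data had equal spread in every group, although the wt arrays varied more. Without replicate 1 of the treated wt arrays at 4 h the interactions called 47 genes in heterozygous and 157 in homozygous cells, and without replicate 1 of the untreated wt arrays 4 and 46.

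The size of the response was compared over genes chosen in the other mutant, so that the choice used the group means of neither side. The calls still used a spread of each gene pooled over all arrays, those of both sides included. Over the 2904 genes called at 4 h in heterozygous cells the slope of the homozygous on the wt fold change was 1.16, with median changes in the called direction of 0.48 in wt and 0.662 log2 in homozygous cells. Over the 3795 genes called in homozygous cells the slope of heterozygous on wt was 1.09, with medians of 0.406 and 0.524. At 24 h the slopes were 0.963 (712 genes, medians 0.832 and 0.85) and 0.937 (867 genes, medians 0.744 and 0.745). At 4 h both the slopes and the medians depended on single wt arrays. Without replicate 1 of the treated wt arrays the slopes were 0.925 and 0.851, with medians of 0.614 in homozygous against 0.535 in wt cells and 0.488 in heterozygous against 0.48 in wt cells. Without replicate 2 of the untreated wt arrays they were 1.006 and 0.949, with medians of 0.622 against 0.553 and 0.5 against 0.492. Without replicate 1 of the untreated wt arrays the medians were 0.622 against 0.328 and 0.5 against 0.286, and without replicate 2 of the treated ones 0.614 against 0.355 and 0.488 against 0.294, with slopes of 1.126 and 1.049 and of 1.213 and 1.168. A slope on the wt change also shrinks where the wt change is noisier.

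**Figure D3:**
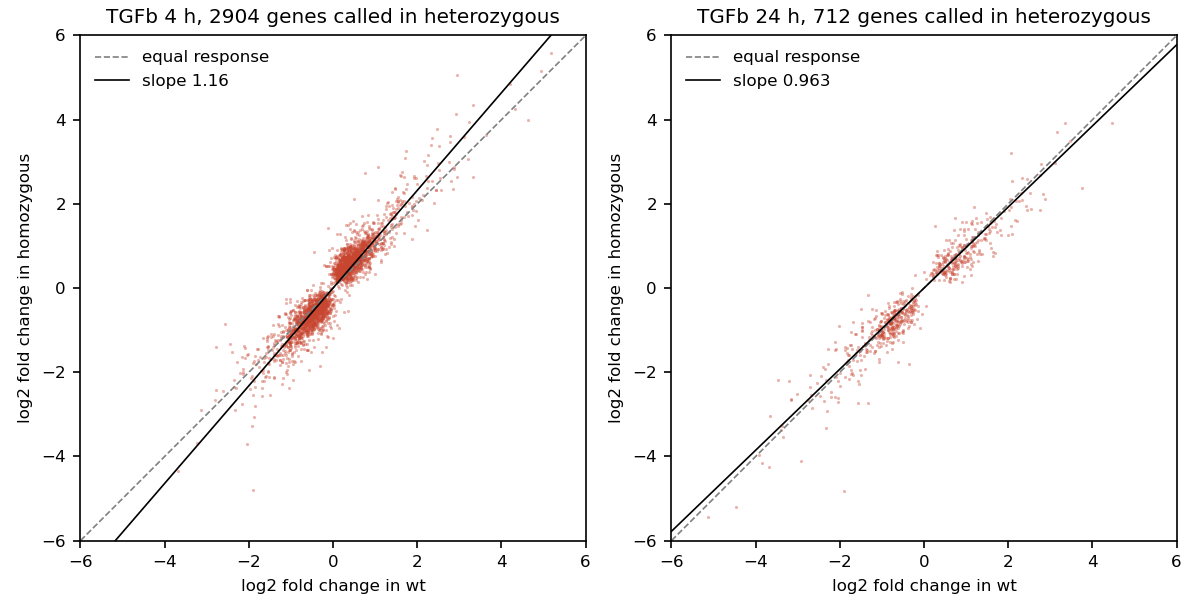
Log2 fold change with TGFb in homozygous cells (vertical axis) against that in wt cells (horizontal axis) at 4 h (left) and 24 h (right); each point is a gene called in heterozygous cells, the dashed line marks equal responses and the solid line the slope through 0. The points follow slopes of 1.16 at 4 h and 0.963 at 24 h.

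Markers of another cell type differed between the genotypes before any comparison of untreated cells. The mean of 11 macrophage and blood cell markers, such as Cd68 and Csf1r, lay between 6.005 and 8.792 log2 in the 6 wt arrays, between 9.45 and 10.57 in the heterozygous and between 9.003 and 9.939 in the homozygous arrays. The arrays also differed in sex-linked genes. Xist, which is expressed from an inactive X chromosome, was at 11.64 log2 in untreated wt replicate 1 and at 1.58 in replicate 2, and the Y-linked Eif2s3y at 3.00 and 10.75. In the treated wt arrays replicate 1 had the Y-linked genes and replicate 2 had Xist, the 6 heterozygous arrays all had Xist, and in homozygous cells replicate 1 had Xist and replicate 2 the Y-linked genes.

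**Figure D4:**
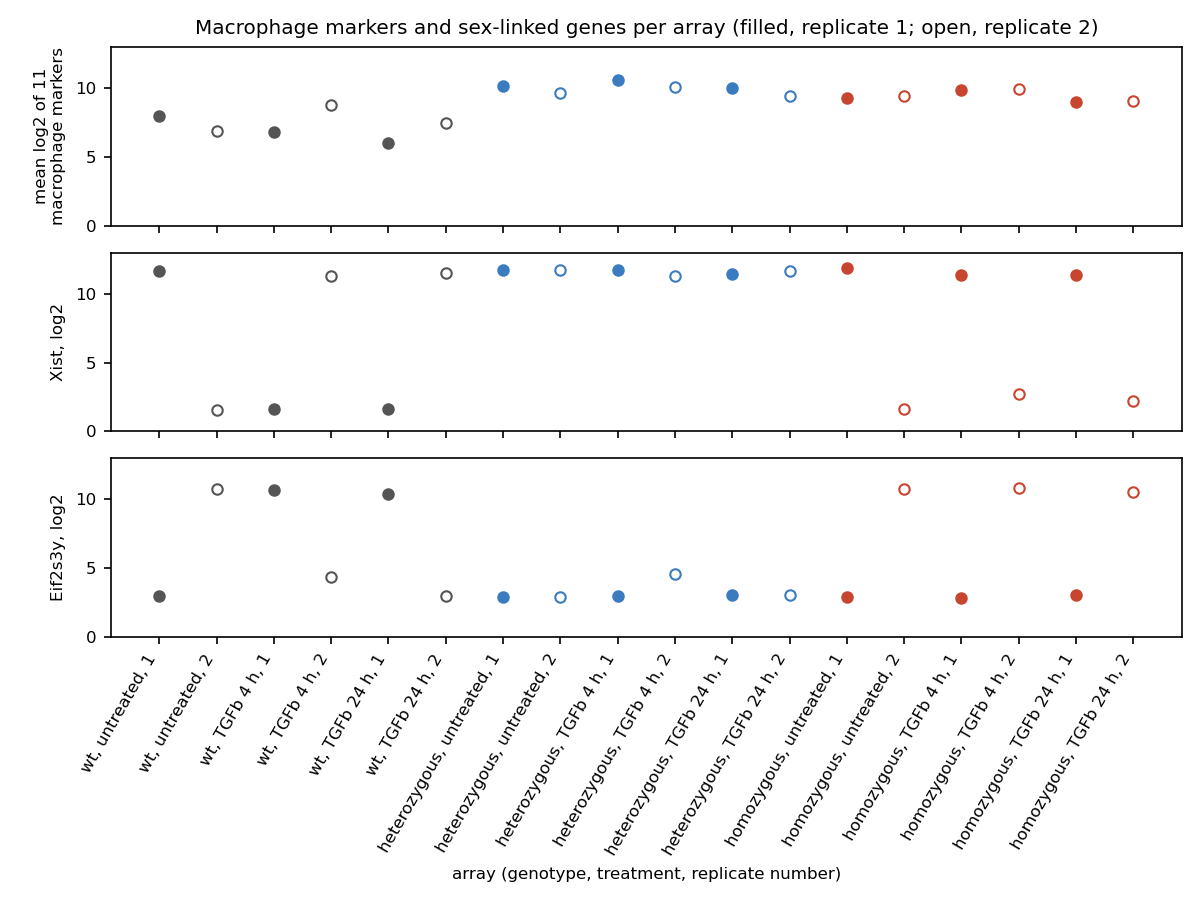
Mean log2 level of 11 macrophage and blood cell markers (top) and log2 levels of Xist (middle) and Eif2s3y (bottom) on the vertical axes for each of the 18 arrays on the horizontal axis, coloured by genotype (grey wt, blue heterozygous, red homozygous), filled for replicate 1 and open for replicate 2. The mutant arrays lie at 9.003 to 10.57 for the markers, above the wt arrays at 6.005 to 8.792, and Xist and Eif2s3y exclude each other.

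Untreated heterozygous cells were compared with untreated wt cells to ask what the mutant changes without added ligand. Genes of macrophages led the difference: Ly86 was higher by 3.50 ± 0.52 (adjusted p = 0.00607), Fcgr3, an Fc receptor, by 3.36 ± 0.63, the lectin Clec4n by 3.34 ± 0.70, the mannose receptor Mrc1 by 3.24 ± 0.65 and Mpeg1 by 3.14 ± 0.64. Cybb, an NADPH oxidase subunit, was at least 5.88-fold higher (0.0261), Clec5a at least 3.30-fold (0.00935), the scavenger receptor Stab1 at least 3.18-fold (4.43e-05) and Pik3ap1 at least 1.22-fold (0.0397). Gatm, an enzyme of creatine synthesis, was higher by 3.49 ± 0.21 (5.18e-06). Lower were Crabp1, a retinoic acid binding protein (-2.36 ± 0.21, 0.000213), Gpr149 (-2.17 ± 0.29), Vegfd (-1.86 ± 0.40), the transcription factor Osr1 (-1.55 ± 0.33), Snhg6 (-1.51 ± 0.17), Zfp760 (-0.997 ± 0.20) and Grb14 (-0.99 ± 0.12). As bounds the potassium channel Kcnn4 was at least 2.53-fold lower (0.0414) and Pax1 at least 1.95-fold (0.00935).

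The 11 macrophage and blood cell markers had a median of 2.504 in untreated heterozygous against wt cells, with 3 higher and 0 lower over all genes and 11 and 0 adjusted over the list alone (camera adjusted p = 8.13e-18, adjusted p = 0.16 with an estimated correlation). TGFb/Smad target and feedback genes had 2 higher, Bhlhe40 (0.63) and Skil (0.46 ± 0.09), and 0 lower of 23 (4 and 0 adjusted over the list alone; 0.000132, and adjusted p = 0.078 with an estimated correlation), with Tgfb1 at 0.46 ± 0.10 (adjusted p = 0.0546). Stress and amino acid response genes had 1 higher of 18, Chac1 at 0.79 (1 adjusted over the list alone; 0.00562, and adjusted p = 0.269 with an estimated correlation). Collagens (median 0.161, camera adjusted p = 0.000132) and interferon-stimulated genes (1.048, 0.000132) were called higher with 0 members past the threshold, and DNA replication (-0.152, 0.0294), skeletal muscle (-1.192, 0.000907) and limb bud genes (-0.251, 0.0232) lower, also with 0. Their adjusted p with an estimated correlation were 0.489, 0.444, 0.783, 0.444 and 0.16, and adjusted over the list alone 1 collagen gene and 2 muscle genes passed. With the mean of these markers as a covariate none of the 7 other lists kept its call in the same direction. This covariate is fitted on differences within pairs of arrays, which were largest in wt. In each wt pair the array with Xist had the higher marker mean (7.952 against 6.861 untreated, 8.792 against 6.849 at 4 h, 7.491 against 6.005 at 24 h). In the wt pairs the effect of the covariate thus cannot be told from that of sex class, and it is carried over to the difference between genotypes. The heterozygous pairs share a sex class, and the homozygous pairs differ in it at nearly equal marker means (9.294 and 9.441 untreated). No fit held this covariate together with one for sex class. TGFb/Smad targets had camera adjusted p = 0.699 at a median of 0.143 in place of 0.161. Above the median of all genes, a value that camera does not use, the list median stood at 0.071 in place of 0.197. The median standard error of the list went from 0.154 to 0.212. Skeletal muscle (median 0.346) had 0.586 and limb bud genes (-0.114) 0.282. Collagens (-0.12, 0.0188) and interferon-stimulated genes (-1.342, 0.000609) were called lower instead, and the medians of DNA replication and stress genes turned to 0.064 and -0.033 without a call. In limma 93 genes passed, 78 higher and 15 lower, but 0 with only the 2 groups in the fit and 37 with array weights. It was 548, 40, 14 and 39 without wt replicate 1, wt replicate 2, heterozygous replicate 1 and heterozygous replicate 2.

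In untreated homozygous against wt cells the same kind of gene led. Clec4n was higher by 3.19 ± 0.70, Mrc1 by 2.99 ± 0.65, Fcgr3 by 2.87 ± 0.63 and Ly86 by 2.63 ± 0.52, and Rac2, a GTPase of blood cells, was called higher (adjusted p = 0.0426) with both group means under the dim level, so without a fold. As bounds Tlr13 was higher at least 3.24-fold (adjusted p = 0.0345), Stab1 at least 2.51-fold (0.000181), the transcription factor Irf8 at least 2.12-fold (0.00388), Clec5a at least 2.02-fold (0.0325) and Pik3ap1 at least 1.22-fold (0.0363). Lower were Crabp1 (-2.63 ± 0.21, 0.000178), Gpr149 (-2.13 ± 0.29), Esm1 (-1.88 ± 0.37), Osr1 (-1.73 ± 0.33), Kcnab1 (-1.73 ± 0.36), the haem synthesis enzyme Alad (-1.67 ± 0.29), Mbnl3 (-1.53 ± 0.25) and S100a4 (-1.499 ± 0.28). Adcyap1r1 was at least 4.32-fold lower (0.028) and Kcnn4 at least 2.53-fold (0.0421). Of the key genes Tgfb1 (0.64 ± 0.10, 0.0123) and Skil (0.43 ± 0.09, 0.0377) passed, and Tgfbr1 (0.30 ± 0.10, 0.137) and Col1a1 (0.43 ± 0.11, 0.0701) did not.

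TGFb/Smad target and feedback genes had 4 higher and 0 lower of 23 in untreated homozygous cells (7 and 0 adjusted over the list alone; camera adjusted p = 5.18e-05, adjusted p = 0.0613 with an estimated correlation). They were Bhlhe40 (0.75), Tgfb1, Pmepa1 (0.51), a TGFb-induced inhibitor of SMAD signalling, and Skil. Collagens and extracellular matrix genes had 2 higher of 26, Eln (1.42) and Thbs2 (0.74) (8 adjusted over the list alone; 5.14e-08, and adjusted p = 0.294 with an estimated correlation), and matrix proteases 1 of 18, Mmp2 at 0.64 (2; 0.0314, and 0.296). Of the receptor, ligand and Smad genes Tgfb2 was higher (0.55) and the activin antagonist Fst lower (-1.09) of 22 (2 and 1 adjusted over the list alone; 0.0188, and adjusted p = 0.345 with an estimated correlation). Stress genes had Chac1 (0.75) higher of 18 (5 higher and 2 lower adjusted over the list alone; 0.0314, and 0.297). The macrophage markers had a median of 1.798 with 0 past the threshold over all genes and 11 higher adjusted over the list alone (1.32e-08, and adjusted p = 0.294 with an estimated correlation).

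A further 7 lists were called in that comparison with 0 members past the threshold over all genes. Collagen processing (median 0.244, camera adjusted p = 0.00341), p53 targets (0.188, 0.0314) and interferon-stimulated genes (1.035, 0.000837) lay higher, and mitosis (-0.268, 0.000123), DNA replication (-0.349, 7.35e-07), cholesterol synthesis (-0.225, 0.0292) and skeletal muscle genes (-1.354, 0.000621) lower. Their adjusted p with an estimated correlation were 0.294, 0.294, 0.328, 0.424, 0.294, 0.631 and 0.3, and adjusted over the list alone 6, 1 and 1 genes of the first 3 were higher and 0, 13, 1 and 6 of the others lower. With the macrophage marker covariate, which has the limit on sex class given above, none of the 12 lists other than the markers themselves kept its call in homozygous cells. TGFb/Smad targets then had a median of 0.162 and camera adjusted p = 0.282, collagens 0.054 and 0.872, mitosis genes -0.025 and 0.59, DNA replication genes -0.21 and 0.052, and interferon-stimulated genes turned to -0.67. The median of receptors, ligands and Smads went from 0.159 to 0.218 (0.156) and that of p53 targets from 0.188 to 0.18 (0.222), so a lost call does not show that the markers account for a list. Over all genes the median went from -0.022 to 0.052 and the median standard error from 0.157 to 0.197. In limma 178 genes passed, 116 higher and 62 lower, but 0 with only the 2 groups in the fit, 10 with array weights and 104 with no filter on dim probe sets. It was 960, 62, 11 and 13 without wt replicate 1, wt replicate 2, homozygous replicate 1 and homozygous replicate 2. Both mutants were compared with the same wt arrays: 48 genes were higher and 10 lower in both, an overlap that the shared arrays raise. The fold changes correlated at r = 0.845 across genes, with a covariance of 0.132. In 20 simulations of unchanged groups with the spread of each untreated group, made after the data were seen, they correlated at 0.798 on average and at most 0.833, with a covariance of 0.0702 and at most 0.0853. The shared, noisier wt arrays can thus give a high correlation by themselves, but in the simulations they did not give all of the covariance. With separate wt arrays for the 2 mutants the covariance was 0.0747 and 0.0546 (r = 0.361 and 0.24). The simulations, with independent noise in each gene, called at most 3 genes in heterozygous and 1 in homozygous against wt.

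Between homozygous and heterozygous untreated cells 0 genes passed in limma, and 340 had an unadjusted p under 0.05. The 5 genes with the smallest p were Tmem87a (-0.94 ± 0.13) and Gatm (-1.41 ± 0.21), both at adjusted p = 0.0785, Pax1, at least 1.54-fold higher in homozygous cells (0.298), the mesenchymal transcription factor Twist1 (0.59 ± 0.12, 0.638) and Eln (0.88 ± 0.19, 0.652). Without the filter on dim probe sets 7 genes passed and with array weights 14. Camera called 8 lists, each with 0 members past the threshold over all genes and none with an estimated correlation. Collagens (median 0.132, adjusted p = 0.317 with an estimated correlation), collagen processing (0.129, 0.262), receptors, ligands and Smads (0.135, 0.262), Wnt and Notch targets (0.125, 0.262) and cartilage and bone genes (0.394, 0.262) lay higher in homozygous cells. DNA replication (-0.209, 0.262), mitosis (-0.148, 0.457) and macrophage markers (-0.522, 0.53) lay lower.

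The genes that TGFb changed at 24 h were then followed in the untreated mutants, taking each list from the other mutant. No array's mean then enters both the list and the comparison. The calls still used a spread of each gene pooled over all 18 arrays. The lists were chosen on these samples. In untreated homozygous against wt cells the 297 genes higher at 24 h in heterozygous cells had a median of 0.199 log2, and 78.5% of them lay above 0 against 46.2% of all genes (camera adjusted p = 4.23e-15, adjusted p = 0.00661 with an estimated correlation). With only the groups compared the unadjusted p with an estimated correlation was 0.0531, with array weights 0.00837, and in the fit of all 18 arrays without weights 0.000413. The 415 genes lower at 24 h had a median of -0.163 (camera adjusted p = 3.61e-05, adjusted p = 0.106 with an estimated correlation). In untreated heterozygous cells the 312 genes higher at 24 h in homozygous cells had a median of 0.102, with 63.1% above 0 against 42.1% of all genes (2.19e-08, and adjusted p = 0.0229 with an estimated correlation). With only the groups compared the unadjusted p with an estimated correlation was 0.199 there, with array weights 0.0717, and in the fit of all 18 arrays without weights 0.00286. The 555 lower genes had a median of -0.132 (0.00504, and adjusted p = 0.184 with an estimated correlation). The lists of the 4 h response lay the other way. Their medians were -0.136 (1578 higher genes) and 0.084 (1326 lower genes) in homozygous cells and -0.125 (2029) and 0.058 (1766) in heterozygous cells. Camera called all of them, with adjusted p = 7.95e-07, 2.69e-06, 2.19e-08 and 6.74e-08. With an estimated correlation the adjusted p were 0.312, 0.184, 0.274 and 0.184. Without replicate 2 of the untreated wt arrays the medians of the higher genes turned to 0.033 and 0.02, and those of the lower genes kept their sign, at 0.044 and 0.046, without a camera call. Leaving out any array kept the 24 h higher lists between 0.121 and 0.252 in homozygous and between 0.012 and 0.171 in heterozygous cells. The lower lists lost their call without replicate 1 of the untreated wt arrays (-0.217 and -0.165), and that of heterozygous cells also without heterozygous replicate 1 (-0.105). With the macrophage marker covariate, and the lists made again under it, the higher and lower lists had medians of 0.161 and -0.071 in homozygous cells. Their unadjusted p were 0.0147 and 0.00162 in camera, and 0.18 and 0.0832 with an estimated correlation, against 0.000413 and 0.0308 without the covariate. In heterozygous cells the medians were 0.017 and 0.103, and camera called neither list.

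**Figure D5:**
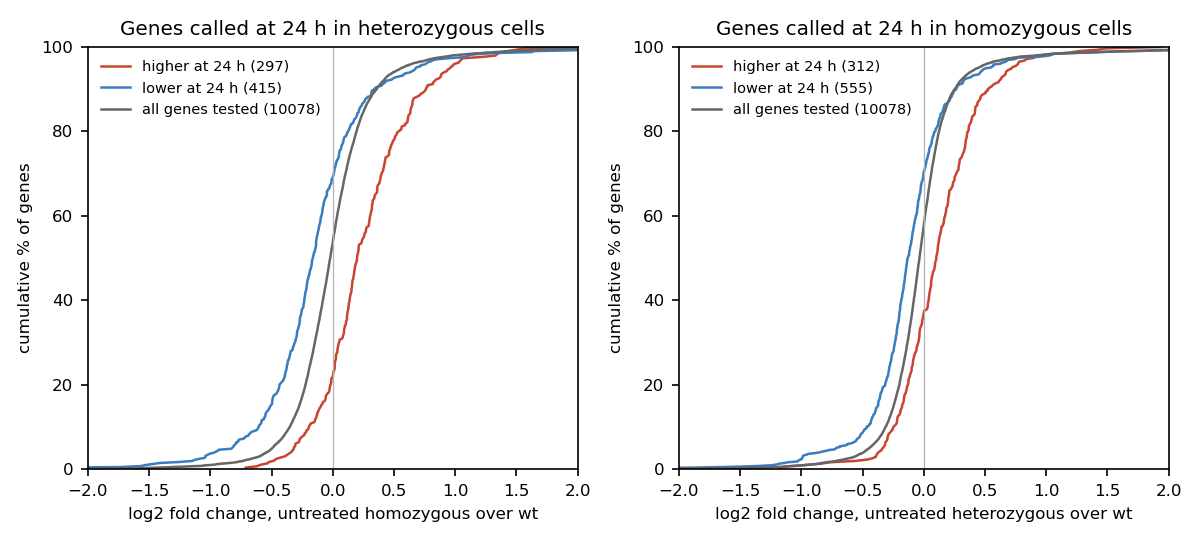
Cumulative percentage of genes (vertical axis) against the log2 fold change of untreated mutant over wt cells (horizontal axis), for homozygous cells on the left and heterozygous cells on the right; red and blue lines are the genes called higher and lower at 24 h of TGFb in the other mutant, grey all 10078 genes. On the left the red line has its median at 0.199 and the blue line at -0.163, and on the right at 0.102 and -0.132.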

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

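The results here were picked out by a rule fixed before the data were examined, a list whose response differed between genotypes in camera at the preset correlation, and no test was chosen for them afterwards. TGFb/Smad target and feedback genes had a negative interaction median in all 4 comparisons: -0.051 (camera adjusted p = 0.00589, adjusted p = 0.188 with an estimated correlation) in heterozygous cells at 4 h and -0.114 (0.000904, 0.123) at 24 h. In homozygous cells it was -0.175 (0.00429, 0.178) at 4 h and -0.08 (0.0287, 0.583) at 24 h. In the untreated mutants 2 (heterozygous) and 4 (homozygous) of the 23 genes passed as higher than in wt. That list was called there at the preset correlation, but not with an estimated one (0.078 and 0.0613) or with the macrophage covariate (0.699 and 0.282, where the medians went from 0.161 to 0.143 and from 0.248 to 0.162). The same untreated arrays enter both values, so a higher untreated level by itself lowers the interaction. Collagens and extracellular matrix genes had -0.128 (0.000451, 0.857) in heterozygous cells at 24 h, and -0.108 (0.00429, 0.977) and -0.209 (0.000251, 0.758) in homozygous cells at 4 h and 24 h. Collagen processing genes had -0.188 (0.0414, 0.977) at 4 h and mitosis genes -0.143 (0.0181, 0.758) at 24 h in homozygous cells. None of these 9 list results was called with an estimated correlation, and 0 of their genes passed in limma.

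A further 6 results concern the response lists taken from the other mutant. At 4 h the genes higher with TGFb had an interaction median of 0.215 (camera adjusted p = 5.76e-15, adjusted p = 0.184 with an estimated correlation) and the lower genes -0.144 (1.36e-17, 0.0458) in homozygous cells, and 0.143 (1.04e-11, 0.214) and -0.073 (6.52e-14, 0.106) in heterozygous cells. At 24 h in homozygous cells the higher genes had -0.063 (0.00834, 0.184) and the lower genes -0.057 (0.0209, 0.248). The larger 4 h response of the mutants depended on single wt arrays in its slopes, which went down to 0.925 and 0.851 with 1 array left out. In that fit the median change was 0.614 in homozygous against 0.535 in wt cells and 0.488 in heterozygous against 0.48 in wt cells, and without the other treated wt array 0.614 against 0.355 and 0.488 against 0.294.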

How the results depend on the processing

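The crossed block, the sex covariate and the macrophage covariate were chosen after the data were seen. Signal over background limits dim genes, and 2 arrays per group limit every p. Without the filter the counts were 104 for homozygous against wt, 7 for homozygous against heterozygous, and 4, 2 and 4 for the interactions heterozygous 4 h, heterozygous 24 h and homozygous 4 h, where more genes were tested, and quantile normalization gave 1 in the last. The mean of a gene's probe sets turned Tgfbr1 to -0.038 and -0.36 and Skil to 0.053 and 0.206 at 4 h in heterozygous and homozygous cells, since other probe sets of these genes point the other way. Equal medians turned Tgfbr1 at 24 h in heterozygous cells to -0.004 (cause not tested).

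Array weights gave 194 and 324 genes for wt at 4 h and 24 h, 1587 for heterozygous at 24 h, and 5860 and 2726 for homozygous at 4 h and 24 h. They gave 37, 10 and 14 for heterozygous against wt, homozygous against wt and homozygous against heterozygous. For 24 h against 4 h they gave 1544 and 5723 in wt and homozygous cells. The lower 24 h list had a median of -0.075 in untreated heterozygous cells and lost its camera call (unadjusted p = 0.277, against 0.00378 without weights). The cause was not tested. Only the groups compared gave 24, 75 and 2037 for wt 4 h, wt 24 h and homozygous 24 h, and 0, 0 and 0 for heterozygous against wt, homozygous against wt and wt 24 h against 4 h. The lower 24 h list in untreated heterozygous cells then had a median of -0.074, also without a camera call (unadjusted p = 0.147). Counts fell where wt arrays, which varied more, were compared and rose in homozygous cells; the cause was not tested.

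The replicate block changed the interaction homozygous 4 h to 1 gene and moved no other count by over 1.5 times. Same-numbered arrays deviated together within genotypes at r = 0.45, 0.45 and 0.38 (heterozygous) and 0.61, 0.6 and 0.54 (homozygous) across genes, and at 0.57 between the treated wt groups, but at -0.49 and -0.66 between untreated and treated wt. Over autosomal genes alone the values were 0.45, 0.45 and 0.37 (heterozygous) and 0.45, 0.41 and 0.38 (homozygous). They were 0.53 between the treated wt groups, and -0.45 and -0.62 between untreated and treated wt. With the sex-linked genes this pattern may reflect pairs within genotypes with the untreated wt numbers crossed, which no label states. With the wt numbers crossed the block within genotype called 2011, 1332 and 1607 genes at 24 h in wt, heterozygous and homozygous cells.

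The sex covariate gave 293 genes for homozygous against wt. The macrophage covariate gave 1826, 1075 and 1348 genes at 24 h in wt, heterozygous and homozygous cells, 422 and 629 for heterozygous and homozygous against wt, of which 28 and 83 had been called without it, and 6 for homozygous against heterozygous. It turned the medians in heterozygous against wt to -0.12 (collagens), 0.064 (DNA replication), -1.342 (interferon-stimulated) and -0.033 (stress), and in homozygous against wt to -0.67 (interferon-stimulated), with 0.029 for stress genes. The response list medians became -0.009 and 0.109 (higher and lower at 4 h) in homozygous and 0.02, 0.143, 0.017 and 0.103 (4 h and 24 h) in heterozygous cells; the cause was not tested.

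Leaving out each array in turn, where the lone array is assumed to vary like the other groups, gave the following lowest and highest counts: wt 4 h 967 to 3382, and wt 24 h 599 to 1881. For heterozygous cells they were at 4 h 1554 to 2082 and 24 h 303 to 443, and for homozygous cells at 4 h 2163 to 2513 and 24 h 379 to 450. They were for heterozygous against wt 14 to 548, homozygous against wt 11 to 960, and 24 h against 4 h 1958 to 4172, 1863 to 2145 and 2054 to 2422 in wt, heterozygous and homozygous cells. The interactions went from 0 to 47, 1, 157 and 4. The response lists went from -0.289 to 0.033, 0.044 to 0.119 and -0.217 to -0.107 (higher 4 h, lower 4 h, lower 24 h) in homozygous and -0.274 to 0.02, 0.036 to 0.093 and -0.165 to -0.05 in heterozygous cells, while the higher 24 h lists kept their calls. Slopes went from 0.925 to 1.213 and 0.907 to 0.983 (homozygous 4 h, 24 h) and 0.851 to 1.168 and 0.868 to 0.982 (heterozygous). The collagen interaction of heterozygous cells at 24 h went from -0.298 to -0.005; causes were not tested. Id1 in wt at 4 h went from -0.17 to 1.345, Tgfbr1 in heterozygous cells at 24 h from -0.021 to 0.084 and Col1a1 in homozygous cells at 24 h from -0.085 to 0.025. Of the values of named genes 3572 kept direction and side of the threshold under other settings, 352 lost the call and 34 gained one, and with an array left out 978, 196 and 15. Of the values of lists 1237 kept theirs and 75 lost the call, and with an array left out 323 and 80.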

Other observations

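All tests of explanations in this part were chosen after the results were seen. For 4 of the 6 the prediction was written before the test's own value was known. It was written after for sex as the cause of the markers and for macrophages in the fall of interferon-stimulated genes. Intervals given with these tests resample genes, not arrays, so they hold no spread between arrays. Lists not described so far held single changed genes. Of 9 BMP target genes 0 passed at 4 h in wt cells and 2 were lower at 24 h, Id4 (-2.12) and Id1, with a median of -0.588. Of 13 Wnt and Notch target genes Jag1, a Notch ligand, rose by 1.13 at 4 h and 1.21 at 24 h, Wnt9a by 2.55 at 24 h, and Notch3 fell by 1.03 at 4 h. Of 14 hypoxia and glycolysis genes 2 rose and 3 fell at 4 h, and Adm, adrenomedullin, fell at 4 h (-1.43) and at 24 h (-2.48). Of 7 neural and glial markers Nes rose by 0.85 at 4 h, and of 13 p53 target genes Btg2 rose by 1.30 at 4 h and Pmaip1 by 1.18 at 24 h. Lists with under 5 measured genes were not tested: of 3 endothelial markers Flt1, a VEGF receptor, rose by 0.78 at 4 h in wt cells, of 4 epithelial markers Krt19 fell by 1.83 at 24 h, and of the liver markers 0 were measured. The 4 measured sex-linked genes gave the array classes described for Xist and Eif2s3y.

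The genes higher in untreated homozygous than in wt cultures were weighed against a difference in cell composition. If more macrophages were the cause, the 113 called autosomal genes other than the 11 markers should lie higher in the treated wt arrays of replicate 2 than of replicate 1, whose markers differ by 1.771 log2. Their median difference was 0.019 (-0.032 to 0.082, all autosomal genes -0.035), so at the median the set did not follow the markers there. The fit that called these genes pooled each gene's spread over all arrays, these pairs included. Genes that differ within pairs get a larger standard error, with a median of 0.629 for the markers against 0.157 for all genes. Such genes are called less often. The test therefore cannot decide whether macrophages are the source of the set. Of the 113 genes 12 lay over 0.5 log2 higher in replicate 2 in both pairs, among them Clec4n, Clec5a, Fcgr3, Irf8 and Rac2. The same held for 313 of all 9746 autosomal genes and for 10 of the 11 markers. Averaged over the heterozygous pairs, untreated and treated, the markers lay 0.509 higher in replicate 1 than in replicate 2. The set lay higher there by 0.081, with 69.9% above 0 against 44.4% of all autosomal genes. Between single arrays of the same sex class the markers were 1.368 and 2.562 log2 higher in homozygous cells, which argues against sex as their source.

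The 24 h response genes that lay higher in untreated homozygous cells might reflect sex or macrophages. Between arrays of the same sex class their shift was 0.19 (0.142 to 0.223) and 0.237, and between the treated wt arrays that differ in macrophage markers it was 0.001 (-0.027 to 0.043) against 0.199 in the mutant. The first of these tests argues against sex as the source. The second cannot decide on RNA of macrophages. Its list was called with a spread of each gene pooled over all arrays, these pairs included. Genes that differ within those pairs are therefore called less often. The second test also does not address macrophages acting through TGFb, since its arrays had received TGFb, and those arrays also differ in sex class. Above the median of all genes the shift was 0.206 against untreated wt replicate 1, with markers at 7.952, and 0.274 against replicate 2, with markers at 6.861. These are single arrays of different sex class, so macrophages, by their RNA or through TGFb, stay open as the source. In heterozygous cells the same test gave 0.002 (-0.025 to 0.036) against a shift of 0.102, and the explanations cannot be told apart there. The macrophage covariate was tried before that test was chosen: with the lists held fixed the medians went from 0.199 to 0.197 and from 0.102 to 0.087, where all genes moved from -0.022 to 0.052 and from -0.036 to 0.072. The lower lists went from -0.163 to -0.109 and from -0.132 to -0.008. With the lists made again under the covariate the homozygous median was 0.161, with unadjusted p = 0.0147 in camera and 0.18 at an estimated correlation. Above the median of all genes it stood at 0.109 in place of 0.221 (0.145 with the list held fixed), and its median standard error went from 0.152 to 0.193. The call with an estimated correlation thus ended with a smaller shift and a larger error. Embryo, litter and line are not separated from genotype in any test.

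With the same covariate single genes of untreated mutant against wt cells moved unequally. In homozygous cells Tgfb1 (0.64 to 0.70, adjusted p = 0.0128), Bhlhe40 (0.75 to 0.55, 0.0362), Pmepa1 (0.51 to 0.50, 0.0263) and Eln (1.42 to 1.11, 0.015) stayed past the threshold, while Skil (0.43 to 0.31, 0.129), Mrc1 (2.99 to 1.28, 0.223) and Fcgr3 (2.87 to 0.73, 0.0756) did not. In heterozygous cells none of these genes passed with it: Tgfb1 (0.46 to 0.53, 0.0847), Bhlhe40 (0.63 to 0.37, 0.213), Pmepa1 (0.29 to 0.28, 0.258), Eln (0.54 to 0.14, 0.802), Skil (0.46 to 0.31, 0.214), Mrc1 (3.24 to 1.05, 0.421) and Fcgr3 (3.36 to 0.62, 0.211).

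The fall of interferon-stimulated genes at 24 h could come from a loss of macrophages under TGFb. The median marker change was 0.099 of the median interferon-gene change in homozygous and 0.037 in heterozygous cells (-0.226 against -2.281 and -0.086 against -2.351). In the mutants this argues against that explanation. In wt cells the ratio was 0.28, above the limit used. That limit was set after the values were known and was applied to the mutants only. A count over all 10078 genes of treated arrays lying on opposite sides of untreated ones in wt and mutant gave 69 (heterozygous) and 132 (homozygous) genes at 4 h and 255 and 503 at 24 h, or 0.685, 1.31, 2.53 and 4.99%, against 5.56% for arrays in random order. On the same side in wt and mutant lay 3794 and 3924 genes at 4 h and 2778 and 2870 at 24 h (37.6, 38.9, 27.6 and 28.5%), against the same 5.56%.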
